A study of Mus musculus with 6 samples.

How the data were processed

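RNA of sorted splenic CD27+ NK cells was hybridised to Affymetrix mouse gene arrays, 1 array per sample, with 3 arrays of the 15a/16-1FKO genotype and 3 of the control genotype. RNA was taken up in Trizol and purified on Directzol columns, per the labels' protocols. The authors deposited 1 table of log2 expression values with 35556 probe sets and 6 arrays. The submitters' processing notes name RMA and Partek 6.6, without saying which step each did. RMA subtracts background, quantile-normalizes the arrays and summarises probes into log2 values. The deposited log2 values lay between 0.74 and 13.6. The genome build is not given in the sources used here, and no scanner files, detection calls or probe sequences were used. RMA compresses differences of dim probe sets, so that folds near background understate the change.

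Probe sets were named from GEO's platform annotation, in which 21789 had 1 gene symbol, 1621 had several and 12146 were not listed. Symbols were checked through Entrez identifiers against the GRCm38.p6 gene table, which changed 0 of them. That table also gave the chromosome and gene order used here, and its coordinates are not printed. Each gene was represented by the probe set with the highest mean over the 6 arrays, which gave 19938 genes, 999 of them with more than 1 probe set. Probe sets with several symbols or none were tested only in an alternative. No filter on dim probe sets was applied. Because the values carry no detection call, the mean level under which 95% of the 1027 olfactory receptor genes lay (4.13) was used to describe the background, a choice made after seeing the data. By this level 10892 genes lay above background.

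Genotypes were compared gene by gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), on the log2 values as deposited, with the genotype as the only term. All differences are knockout minus control. Adjusted p-values are Benjamini-Hochberg values over 19938 genes, with a threshold of 0.05, and 95% intervals come from the same fit. There is 1 contrast in the design. The lists of genes were written before the data were examined: 24 lists of NK stages, effectors, receptors, transcription factors, signalling, cell cycle, stress, other cell types, published microRNA-15/16 targets, MYB-activated genes and the host loci. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 24 lists, then with an estimated correlation and with fry. With an estimated correlation 0 lists passed, and with fry 0 lists passed. Myb enters 2 lists and is named in the study's title, so that its inclusion is not independent of the study.

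The genes named in the text follow a rule fixed in advance: up to 12 rising and 12 falling genes past the threshold without overlap between genotypes leaving out predicted genes, receptor families and small RNAs (3 passed, all rising), the 4 members of each list with the smallest p, and 29 genes of interest. A few further list members, Xist, Y-linked genes and genes of the deleted locus's chromosome were named after their values were seen. The planned test of genes with microRNA-15/16 seed matches in their 3' UTRs needs transcript sequences and was not run.

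Limma and camera were tested on simulated data drawn from the mean and the spread of each of the 19938 genes, in 10 simulations with 200 changed genes each. Of the changed genes, 1.34% were called at a log2 change of 0.5, 52.2% at 1 and 92.6% at 2, with 3.6 false calls per simulation. False calls were counted over all other genes, including the few that were shifted as lists. For a list of 17 genes shifted by 0.2, camera gave an unadjusted p under 0.05 in 9 of 10 simulations, and for an unshifted list in 1 of 10, with independent noise between genes. Replicate numbers appear in both genotypes. Neither the labels nor the check of same-numbered arrays settled whether these numbers pair the arrays, and the model without a block, chosen before the data were examined, was kept.

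Alternatives tried were centring on array medians, a second quantile normalization, genes at or above the median brightness, the replicate number as a block, a trended and robust prior, array weights, each array left out in turn, every probe set with 1 symbol, every probe set of the table, and the dimmer probe set of each gene. Added after seeing the data were a covariate for sex-linked transcripts (Xist minus the mean of Eif2s3y, Kdm5d and Uty) and lists without genes on the chromosome of the deleted locus.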

Results

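Expression was profiled in 6 microarrays of natural killer (NK) cells sorted from the spleens of mice as YFP+, CD27+, NK1.1+ and CD3-negative. NK cells are innate lymphocytes that kill infected or transformed cells. CD27 marks their less mature stages, and CD11b (encoded by Itgam) and KLRG1 are acquired as they mature. The design held 3 arrays of the genotype labelled 15a/16-1FKO, called the knockout here, and 3 arrays of control cells (Ctrl). The design text calls the arrays of a genotype technical replicates, so that p-values measured only the spread between these arrays. The comparison addressed what the loss of microRNA-15a and microRNA-16-1 changes in CD27+ NK cells, and the study's title names the transcription factor c-Myb (Myb) as a target. Across 19938 genes, arrays of the same genotype correlated with r between 0.982 and 0.984 in 6 pairs. Arrays of different genotypes correlated with r between 0.981 and 0.987 in 9 pairs. The medians of the 6 arrays over all probe sets lay between 4.23 and 4.33 on the log2 scale. Microarray values carry no read depth, and the number of arrays limited the precision.

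The deleted locus separated the genotypes. The probe set annotated to Mir15a, the precursor gene of microRNA-15a, had a log2 level of 6.62 ± 0.56 in control cells and 3.77 ± 0.52 in knockout cells (mean ± SD, n = 3 arrays each). It was the only gene that fell past the threshold, with a level 7.18-fold higher in control cells (limma, log2 difference -2.84, SE 0.31, adjusted p = 0.0296). The probe set of Mir16-1 was lower in all 3 knockout arrays, at 2.76 ± 0.21 against 3.39 ± 0.33, with a log2 difference of -0.63 (unadjusted p = 0.00922 by limma, adjusted p = 0.999). Both means of Mir16-1 and the knockout mean of Mir15a lay under 4.13, the level below which 95% of 1027 olfactory receptor genes lay, so these differences were measured near the array's background. The call for Mir15a ended when any of 4 single arrays was left out, the knockout replicates 2 and 3 and the control replicates 1 and 3, with log2 differences between -2.58 and -2.81.

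The second copy of the family and the neighbours of the deleted locus did not pass the threshold. Mir15b and Mir16-2, which form the related cluster within Smc4, had log2 differences of -0.29 (SE 0.22) and -0.11 (SE 0.15), with means under the olfactory receptor level. Smc4, a condensin subunit and the host gene of that cluster, had a difference of 0.00 (95% interval -0.37 to 0.38). The Dleu2 probe set was near background in both genotypes, with a difference of 0.62 (SE 0.37). Kcnrg, a neighbour of the deleted locus, had a difference of 0.79 (SE 0.25) and Spryd7 one of 0.39 (SE 0.16), each higher in all 3 knockout arrays. Of the 13 genes in the list of host loci and neighbours, 0 rose and 1 fell over all genes tested, and 0 rose and 1 fell adjusted over the list alone, in both counts Mir15a. The list's median was 0.01 but its mean was -0.13, and its camera adjusted p was 0.77. Over all 24 lists, the members that passed when adjusted over the list alone were Mir15a, Kit in 2 lists and Gzmc in 2 lists.

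Across the transcriptome, 3 genes rose and 1 fell in the knockout. Gfra2, a co-receptor for neurturin, rose 3.85-fold, from 4.79 ± 0.08 to 6.74 ± 0.09 (mean ± SD, n = 3 arrays each). Mtmr9, a catalytically inactive myotubularin-related protein, rose 3.71-fold, from 6.31 ± 0.05 to 8.21 ± 0.21. Rcbtb2, a protein with RCC1 and BTB domains, rose 2.44-fold, from 5.14 ± 0.13 to 6.43 ± 0.14. The adjusted p-values by limma were 0.00143 for Gfra2, 0.00257 for Mtmr9 and 0.0296 for Rcbtb2. A second probe set of Mtmr9 gave a log2 difference of 1.91 (SE 0.17), beside 1.89 (SE 0.15) for the first. All 4 called genes lie on 1 chromosome in the GRCm38.p6 gene table, the one that carries the deleted locus. Mtmr9 was the 19th measured gene from Mir15a in gene order, Gfra2 the 104th and Rcbtb2 the 107th, all on the same side. The call for Rcbtb2 ended when any 1 of the 6 arrays was left out, with log2 differences between 1.21 and 1.35, and with the replicate number as a block (limma adjusted p = 0.0715), while Gfra2 and Mtmr9 passed the threshold in each of these fits. When all 35556 probe sets of the table were tested, named or not, 0 passed the threshold by limma.

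**Figure D1:**
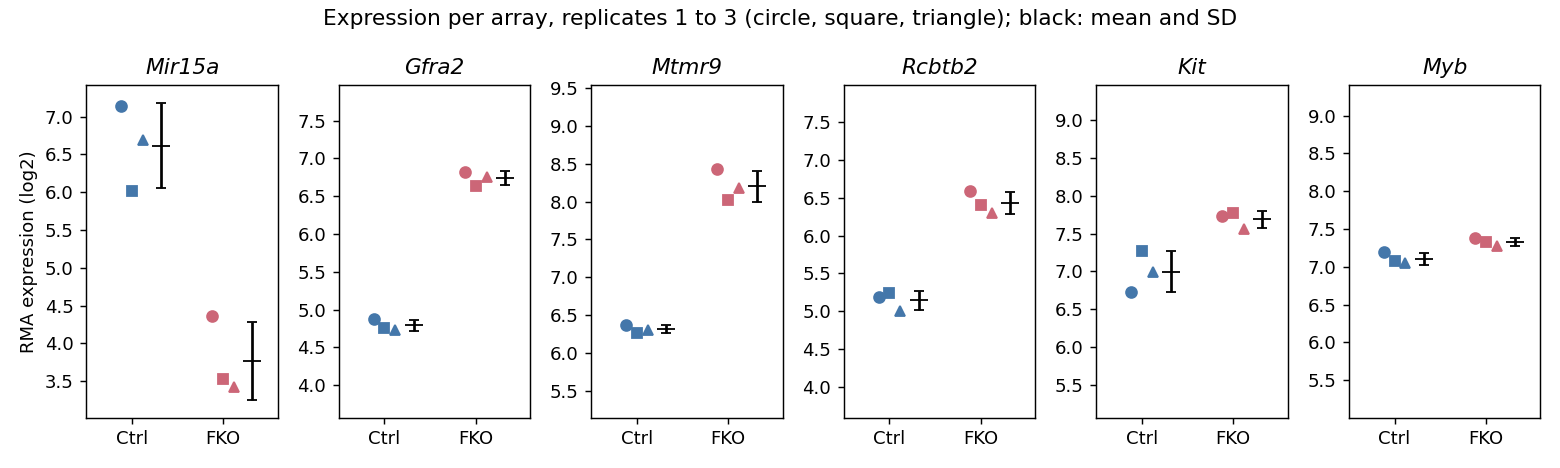
RMA expression (log2, each axis spanning the same range) of 6 genes in each array, with control arrays in blue, 15a/16-1FKO (FKO) arrays in red, symbols for replicate numbers and black bars for mean and SD (n = 3). The 2 genotypes do not overlap in any of the 6 genes, and the difference of means is largest for Mir15a (log2 difference -2.84) and smallest for Myb (0.22).

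**Figure D2:**
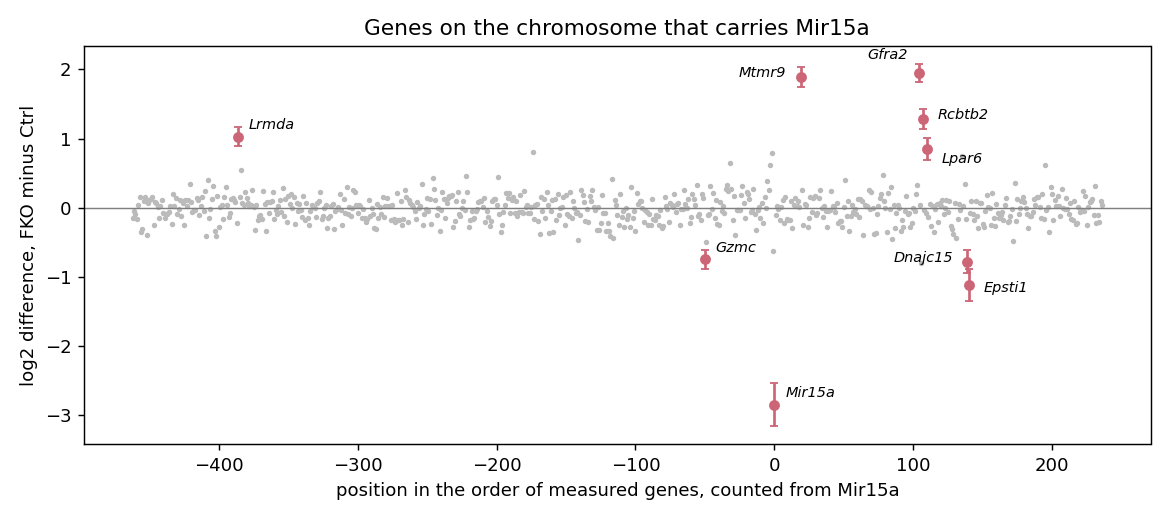
Log2 difference (15a/16-1FKO minus Ctrl) of every measured gene on the chromosome that carries Mir15a, by position in gene order counted from Mir15a. Red points with SE bars are genes with an unadjusted limma p under 0.001, among them Mir15a at -2.84, Mtmr9 at 1.89 and Gfra2 at 1.95, and grey points are all other genes.

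Outside these genes no difference passed the threshold, though some were large against the spread between arrays. Lrmda, for example, differed by 1.03 (SE 0.14, limma adjusted p = 0.102). An unadjusted p under 0.05 was reached by 691 genes, 310 higher and 381 lower, where 997 would be reached by chance. The arrays of the genotypes did not overlap in 8.33% of genes, where chance gives 10%. Other splits of the 6 arrays into groups of 3 gave 715 to 1691 genes with an unadjusted limma p under 0.05. Both chance values assume independent arrays, and neither count was made with the replicate number as a block. In data simulated from the means and spreads of these 19938 genes, each simulation held 200 changed genes. Of those changed by 1 on the log2 scale 52.2% were called, and of those changed by 0.5, 1.34%. With fewer changed genes the adjusted threshold is stricter, so these shares may overstate detection here. The simulations thus mostly missed changes of 0.5 on the log2 scale. They took the spread of each gene between these arrays as its true spread, and what that does to detection was not tested.

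Published targets of microRNA-15/16 did not pass the threshold one by one or as a list. Myb, the transcription factor named in the study's title, was at 7.33 ± 0.05 in knockout and 7.11 ± 0.08 in control arrays (n = 3 each) and was higher in all 3 knockout arrays. Its log2 difference was 0.22 (95% interval -0.07 to 0.51, adjusted p = 0.999 by limma). An exact two-sided permutation test without pairing gave p = 0.1, the smallest value that 3 against 3 arrays allow. Between arrays of the same number Myb differed by 0.18, 0.24 and 0.23. With the replicate number as a block the SE was 0.14 (limma adjusted p = 0.999). Limma moves each gene's variance toward a value shared by all genes. The interval and this SE are therefore wider than the spread of Myb alone would give. The D-type cyclin Ccnd3, which drives G1 progression, was higher in all 3 knockout arrays, with a log2 difference of 0.32 (95% interval 0.02 to 0.62). Ccnd1 differed by 0.23 (SE 0.17), Cdc25a by 0.21 (SE 0.16), the anti-apoptotic Bcl2 by 0.14 (SE 0.15) and Cdk6 by 0.12 (SE 0.19). Ccnd2 differed by -0.08 (SE 0.15), Ccne1 by 0.03 (SE 0.17), and the checkpoint kinases Wee1 and Chek1 by 0.04 each (SE 0.24 and 0.19, respectively). Of 29 measured targets, 17 had a positive and 12 a negative difference, with a median of 0.03, and the list's adjusted p was 0.413 (limma's camera). No target passed over all genes or adjusted over the list alone, and 1 of 29, Ccnd3, had an unadjusted p under 0.05. Myb and Ccnd3 were the only 2 of 29 without overlap between genotypes, where 8.33% of all genes had none. Of the 11 measured genes activated by MYB, 5 had positive and 6 negative differences, with a median of -0.04 but a mean of 0.02 and a camera adjusted p of 0.707. One of these 11, Kit, passed when adjusted over the list alone, while the progenitor marker Cd34 (-0.33, SE 0.20, near background) and the repressor Gfi1 (-0.10, SE 0.13) had negative differences.

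Genes of the CD27-positive, CD11b-negative stage, the immature end of the CD27+ gate, were the only list past camera's threshold. Of its 17 measured genes, 15 had a positive difference, with a median of 0.21, and the list was higher in the knockout than other genes (camera with its preset correlation of 0.01, adjusted p = 4.47e-05). The call was lost when the correlation was estimated (adjusted p = 0.467 with an estimated correlation, unadjusted p = 0.0195). The mean over the list was 8.12 ± 0.11 in knockout and 7.87 ± 0.06 in control arrays (n = 3 each), and the arrays of the genotypes did not overlap. Kit, the stem cell factor receptor carried by immature NK cells, had the largest difference, 0.69 (95% interval 0.32 to 1.06, adjusted p = 0.999 over all genes), and alone passed when adjusted over the list alone (adjusted p = 0.0362, limma). It was followed by the lymphotoxin subunit Ltb at 0.51 (SE 0.28), the signalling suppressor Socs2 at 0.48 (SE 0.32), the membrane glycoprotein Emb at 0.43 (SE 0.18) and Ctla2b at 0.35 (SE 0.16). The interleukin-7 receptor Il7r differed by 0.33 (SE 0.22), the chemokine receptor Ccr2 by 0.32 (SE 0.15) and Cd27 itself, which was gated on, by 0.09 (SE 0.18). A second probe set of Socs2 differed by 0.00 (SE 0.21). Each of the 10 ways to split these 6 arrays into groups of 3 gave between 1 and 5 lists past camera's threshold.

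Genes of the mature, CD11b-positive and CD27-negative stage did not pass as a list. Of 18 measured genes, 14 had a negative difference, with a median of -0.07 (camera adjusted p = 0.189, and 0.806 with an estimated correlation). The smallest unadjusted p-values in the list were those of the ectonucleotidase Entpd1 at -0.65 (SE 0.32), granzyme B (Gzmb) at -0.50 (SE 0.17), the transcription factor Irf8 at -0.36 (SE 0.19) and the mast cell chymase Cma1 at -0.22 (SE 0.15). The defining markers had differences near 0, with Itgam (CD11b) at 0.02 (95% interval -0.38 to 0.43), Klrg1 at 0.02 (SE 0.26) and the maturation factor Zeb2 at 0.01 (SE 0.18). The list passed in the fits without knockout replicate 1 (camera adjusted p = 0.00717) and without control replicate 3 (adjusted p = 0.0162). Gzmb and Cma1 lie on the chromosome of the deleted locus.

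**Figure D3:**
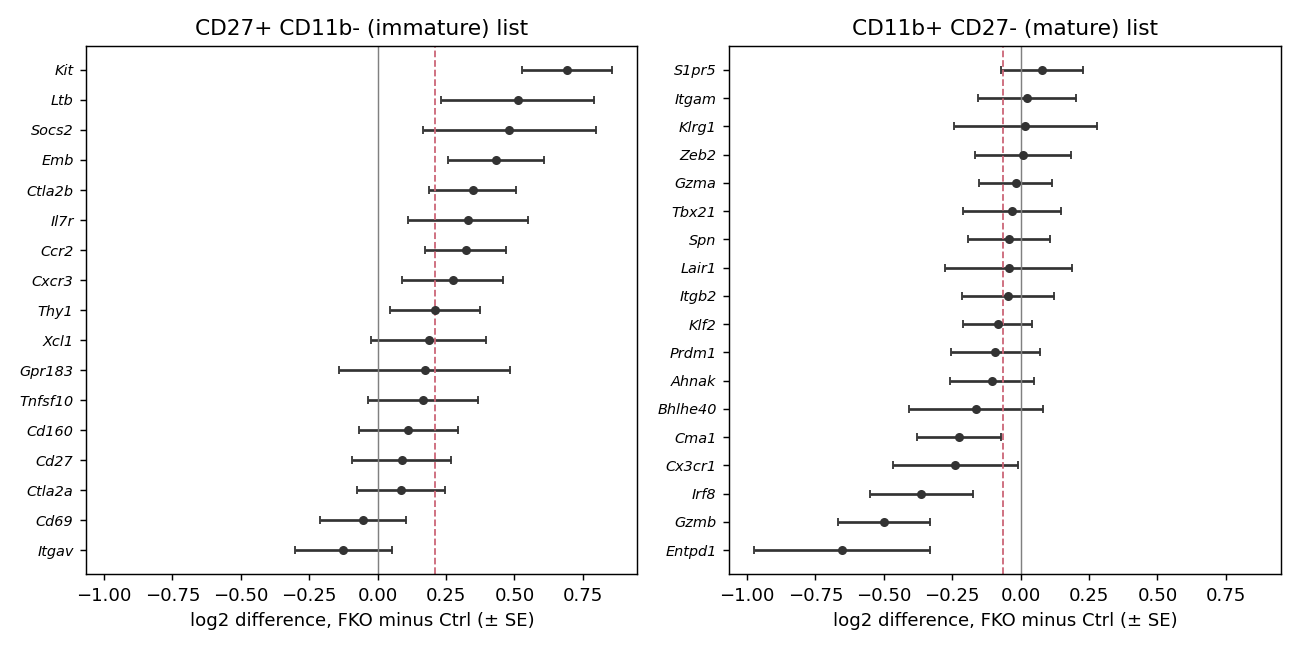
Log2 difference (15a/16-1FKO minus Ctrl) of each measured gene of the immature (left) and mature (right) NK lists, with SE bars and a dashed line at the median of the list. The medians are 0.21 and -0.07, and 15 of 17 and 4 of 18 genes lie above 0.

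Effector genes went both ways and none passed over all genes tested. Of 22 genes for cytotoxicity and cytokines, 11 had positive and 11 negative differences (camera adjusted p = 0.662), with 0 higher and 1 lower adjusted over the list alone. That gene was granzyme C (Gzmc), with a log2 difference of -0.74 (SE 0.14), although its means of 2.78 and 3.52 lay under the olfactory receptor level. Gzmb was lower in all 3 knockout arrays, at 8.40 ± 0.23 against 8.90 ± 0.20 (n = 3 each), and granzyme K (Gzmk) higher in all 3, with a difference of 0.53 (SE 0.16). Interferon-gamma (Ifng) was lower in all 3 knockout arrays, with a difference of -0.30 (95% interval -0.65 to 0.04). Perforin (Prf1) differed by -0.14 (SE 0.17). Gzmb and Gzmc are adjacent among measured genes and lie on the chromosome of the deleted locus.

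Receptors and transcription factors of NK cells did not pass as lists with all 6 arrays. The activating receptor Ncr1 differed by 0.05 (95% interval -0.29 to 0.38) and Klrb1c, which encodes the NK1.1 antigen used in the sort, by 0.01 (95% interval -0.29 to 0.31). Of 28 measured receptors and adaptors, 21 had positive differences, with a median of 0.05 (camera adjusted p = 0.321). The costimulatory receptor Slamf6 had the largest, 0.77 (SE 0.29), followed by Klrb1f at 0.27 (SE 0.15) and Klrc1 at 0.21 (SE 0.15), while the inhibitory receptor Lag3 differed by -0.27 (SE 0.17). That list passed only in the fit without knockout replicate 3 (camera with its preset correlation, adjusted p = 0.0298). With all 6 arrays its estimated correlation was 0.19 (camera adjusted p = 0.806). Some killer lectin-like receptors, such as those of the Klra family, are closely related in sequence, so that probes can be shared between them. Among 24 NK transcription factors, 12 had positive and 12 negative differences with a median of 0.00 and a mean of 0.01 (camera adjusted p = 0.668). The T-box factors Tbx21 and Eomes differed by -0.03 (SE 0.18) and 0.20 (SE 0.16), Foxo1 by 0.25 (SE 0.19), Zbtb32 by -0.26 (SE 0.16) and Bcl11b by -0.19 (SE 0.15).

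Cytokine signalling, migration and innate lymphoid genes did not pass as lists either. The STAT-induced suppressors Socs3 and Cish were lower in all 3 knockout arrays, by -0.52 (SE 0.18) and -0.34 (SE 0.15), while the receptor subunit Il10rb differed by 0.36 (SE 0.21). A second probe set of Socs3 differed by 0.34 (SE 0.20), the opposite way. Of 24 measured cytokine receptor and signalling genes, 15 had positive differences (camera adjusted p = 0.532). Among 20 migration and adhesion genes, 13 had positive differences with a median of 0.06 (camera adjusted p = 0.272). They included the integrin Itga1 at 0.51 (SE 0.17), the egress receptor S1pr1 at 0.49 (SE 0.20) and Cd44 at 0.32 (SE 0.17). The control mean of Itga1, 3.88, lay under the olfactory receptor level. The 13 measured genes associated with type 1 innate lymphoid cells (ILC1) had 7 positive and 6 negative differences (camera adjusted p = 0.77). In that list Gzmc alone was lower adjusted over the list alone.

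None of the lists for cell cycle, survival, stress and respiration passed with all 6 arrays. Of 37 genes of G1/S and DNA replication, 20 had positive and 17 negative differences (camera adjusted p = 0.533). They included thymidine kinase Tk1 at 0.66 (SE 0.27), the clamp loader subunit Rfc3 at -0.45 (SE 0.18) and the cyclin Ccne2 at -0.45 (SE 0.18). A second probe set of Tk1 differed by -0.07 (SE 0.23). Of 39 genes of G2/M and mitosis, 19 had positive and 20 negative differences (camera adjusted p = 0.712). The cyclin Ccna2 at -0.75 (SE 0.34), Cdca3 at -0.63 (SE 0.22), Bub1b at -0.38 (SE 0.16) and Cdca8 at -0.36 (SE 0.19) had the smallest p-values among them. The knockout mean of Bub1b, 3.94, lay under the olfactory receptor level. Of 13 BCL2 family genes, 8 had positive differences (camera adjusted p = 0.502), led by the pro-apoptotic Bcl2l11 at 0.35 (SE 0.18) and Bik at 0.38 (SE 0.21). Of 15 targets of p53, 10 had positive and 5 negative differences (median 0.05, camera adjusted p = 0.502). Of 25 interferon-stimulated genes, 8 had positive and 17 negative differences (median -0.06, camera adjusted p = 0.668), and of 29 immediate early and heat shock genes 10 and 19 (median -0.05, camera adjusted p = 0.502). Among the interferon-stimulated genes, Oas2 differed by 0.44 (SE 0.13) and Dhx58 by -0.59 (SE 0.15), both near background. The 31 genes of oxidative phosphorylation had a median of -0.03 (camera adjusted p = 0.533). They passed only in the fit without control replicate 1 (camera with its preset correlation, adjusted p = 0.000947). With all 6 arrays their estimated correlation was 0.30 (camera adjusted p = 0.859).

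Markers of other cell types did not pass as lists. The median differences were -0.03 for 16 B cell markers, -0.01 for 16 T cell markers and -0.08 for 20 macrophage, monocyte and dendritic cell markers. They were 0.01 for 12 neutrophil, -0.08 for 6 erythroid and -0.11 for 9 platelet and megakaryocyte markers. Camera adjusted p-values of these lists lay between 0.316 (platelets) and 0.668 (T cells), and 0 markers passed over all genes or adjusted over the list alone. The median and the test had opposite signs for T cell markers, whose mean was 0.03. By unadjusted p, the leading markers were the neutrophil gene S100a8 at 0.77 (SE 0.32), the class II gene H2-Ab1 at -0.58 (SE 0.20), Cd28 at 0.43 (SE 0.14) and the platelet gene Gp5 at -0.36 (SE 0.13). The means of H2-Ab1 and Gp5 over the 6 arrays lay under the olfactory receptor level.

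Transcripts that depend on the sex of the animal differed between arrays of one genotype. Xist, which is transcribed from the inactive X chromosome of female cells, ranged from 3.89 to 9.65 on the log2 scale across control arrays and from 7.56 to 8.84 across knockout arrays. Its spread within a genotype (SD 2.26) was the largest of all 19938 genes, whose median SD was 0.20. The Y-linked Eif2s3y ran the opposite way, at 2.33 in control replicate 1, where Xist was highest, and 7.95 in control replicate 2, where Xist was lowest. These 2 control arrays stood apart, while the other 4 arrays held Xist at 7.56 or more together with Eif2s3y at 6.18 or more. With an index of these transcripts as a covariate, a choice made after seeing the data, 2 genes passed the threshold, Gfra2 and Mtmr9. The log2 differences of Mir15a and Rcbtb2 were then -2.85 and 1.29, close to those without it. The adjusted p-values by limma were 0.0545 for Mir15a, 0.0753 for Rcbtb2 and, for the immature NK list (camera, preset correlation), 1.34e-05. Without the covariate, an estimated correlation ended the list's call (camera adjusted p = 0.467). The mean of the index was 2.60 in knockout and 2.51 in control arrays, so the covariate could hardly move any difference.

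**Figure D4:**
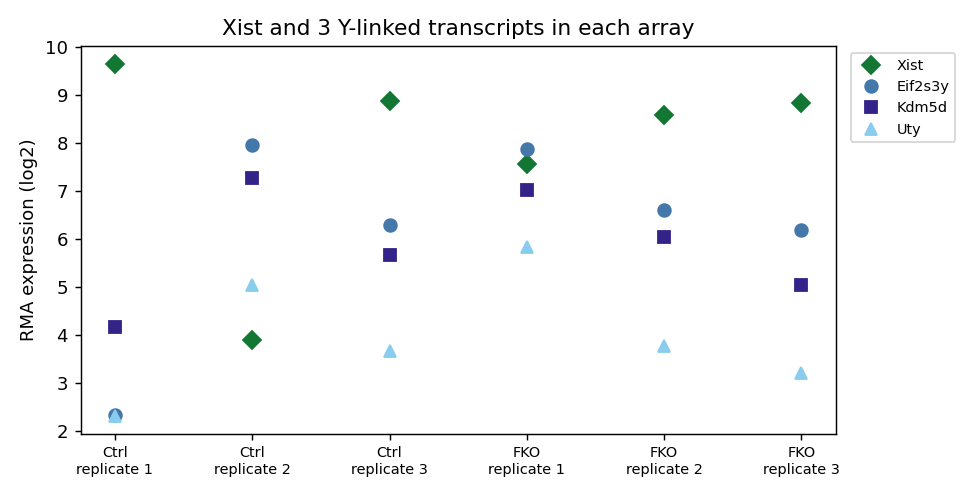
RMA expression (log2) of Xist and of the Y-linked Eif2s3y, Kdm5d and Uty in each of the 6 arrays (FKO, 15a/16-1FKO). Control replicate 1 has the highest Xist (9.65) and the lowest Eif2s3y (2.33), control replicate 2 the lowest Xist (3.89) and the highest Eif2s3y (7.95), and the other 4 arrays hold both.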

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

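Of the alternatives, the sex-linked covariate and the lists without the deleted locus's chromosome were chosen after seeing the data. Against 4 genes past the threshold (3 higher, 1 lower), centring, a second quantile normalization, genes at or above the median brightness and array weights each gave the same 4 genes, and every probe set with 1 symbol gave 5 probe sets of the same 4 genes. The replicate block and the trended, robust prior each gave 3, without Rcbtb2 (adjusted p = 0.0715 and 0.0542). Leaving out 1 array gave 2 to 3 genes, of which 2 higher and 0 to 1 lower, always including Gfra2 and Mtmr9. The sex-linked covariate gave 2 genes, with 0 lower. Testing every probe set of the table gave 0 genes, 0 higher and 0 lower, so that Gfra2 and Mtmr9 lost their calls there too. Their unadjusted limma p-values in the main fit, 7.19e-08 and 2.58e-07, would pass over 35556 tests. The number of tests alone is thus not the cause. Limma's variance shared between probe sets also differs in that fit, and its part was not tested. Deviations of same-numbered arrays from their genotype means correlated with r of 0.05, 0.15 and 0.14 over all genes. Over genes at or above the median brightness r was 0.14, 0.22 and 0.18. In both sets 6 of 6 arrays correlated best with their own number, a hint of pairing from the data, not from the design. The deviations of a genotype sum to 0 and the gene sets overlap, so these matches are not independent. How often chance gives them was not computed. The block changed no call of a named gene or list other than Rcbtb2. The immature NK list stayed past the threshold in every fit with the preset correlation, with camera adjusted p from 5.90e-06 (without knockout replicate 3) to 0.0132 (without knockout replicate 1), but not with an estimated correlation (0.467) or fry (0.805). The count of lists, 1, became 1 to 2 when an array was left out, and 0 with an estimated correlation or fry. No called gene or list changed direction under any alternative run. Among values of single named genes under the other alternatives, leaving aside those that test every probe set, 1389 kept their side of the threshold and 14 lost it, all for Mir15a or Rcbtb2. Among those of the other lists, 363 kept it and 4 came to pass, each with 1 array left out. Named genes other than the 4 called had limma adjusted p of 0.842 (Gzmc) or more in the main fit, far from the threshold. A change of sign without a call was counted as kept. The count of 1389 therefore says little about the uncalled genes. The seed-match alternatives were not run. Signal near background limits Mir16-1, Mir15b, Mir16-2, Dleu2, Gzmc, Chek1, Cd34, Oas2, Dhx58, H2-Ab1 and Gp5, and in 1 genotype also Mir15a, Itga1 and Bub1b.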

Other observations

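The tests of gene location, of the sex-linked transcripts, of Itgam and of the sex-linked covariate were chosen after the results were seen; those of other splits of the arrays and of the immature list without its leading genes were fixed before their results were seen. Beyond the 4 called genes, 5 further genes on the chromosome of the deleted locus had an unadjusted p under 0.001. They were Lrmda with a log2 difference of 1.03 (SE 0.14), the lysophosphatidic acid receptor Lpar6 at 0.85 (SE 0.16), the mitochondrial chaperone Dnajc15 at -0.78 (SE 0.16), Epsti1 at -1.11 (SE 0.23) and Gzmc at -0.74 (SE 0.14). Their adjusted p-values by limma were 0.102 for Lrmda, 0.842 for Lpar6 and Gzmc, and 0.999 for Dnajc15 and Epsti1, so that none of the 5 passed the threshold. Dnajc15 and Epsti1 are direct neighbours among measured genes, the 139th and 140th from Mir15a, and both were lower in all 3 knockout arrays. Elsewhere in the genome the genes with an unadjusted p under 0.001 were Cdk7, H2-M1, Mir3068, Nbea, Sympk, Tmtc1 and Tonsl. Among these, Nbea differed by -1.20 (SE 0.16, limma adjusted p = 0.102) with means near background, and Sympk, a scaffold of mRNA 3' end processing, by 1.09 (SE 0.19, adjusted p = 0.592). As for the number of called genes, 1 of the 10 splits of the arrays, the real one, gave 4, the highest other giving 1, and 10 splits are too few for a share under 0.05.

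Genes with small p-values gathered on the chromosome of the deleted locus, where, without Mir15a and Mir16-1, 8 of the 15 placed genes with an unadjusted p under 0.001 lay, 5 higher and 3 lower, against 0.527 expected from the 3.51% of genes it carries (two-sided Fisher's exact test, p = 1.15e-08). Without the called genes, whose place prompted the test, 5 of 12 lay there where 0.42 would be expected (Fisher's exact test, p = 3.32e-05). Genes reached only through the lost microRNAs would be spread over all chromosomes, so the table argues against such an effect in trans as the cause of the whole group, though not of any single gene. DNA linked to the targeted allele, from the strain in which it was made or through effects in cis, is a candidate explanation. The 8 genes lay on average 131.9 measured genes from Mir15a against 194.3 for the rest. A one-sided permutation test left this gap open (p = 0.081). Lrmda lay farthest, at -386 in gene order from Mir15a, and raised the mean of 131.9. The others of the 8 lay between -50 (Gzmc) and 140 (Epsti1). In 1 of the 10 splits of the arrays, the real one, were as many as 8 such genes found, the highest other being 3, with 10 splits too few for a share under 0.05, and whether linked variants changed expression or the match to the probes was not tested.

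Genes of the immature NK stage were higher in the knockout as a list with camera's preset correlation, but not with an estimated correlation (adjusted p = 0.467) or by fry (adjusted p = 0.805). Without Kit, Emb and Ctla2b the other 14 genes still had a positive median, 0.18. Their unadjusted camera p was 0.000794 at the preset correlation. In 2 other splits of the arrays the whole list, not these 14 genes, reached camera p-values of 0.000704 and 0.000768. The 14 genes alone were not tested in other splits. Their p thus has no like value beside it and cannot decide whether they differ with genotype. The covariate for sex-linked transcripts gave no test of the sex mix, since its mean was 2.60 in knockout and 2.51 in control arrays, so that it moved the 110 named genes by at most 0.0104 on the log2 scale and left the list's median at 0.209. A larger share of CD11b-negative cells in the sorted CD27+ population may contribute, but Itgam, which should then be lower, differed by 0.0237 with an interval of -0.38 to 0.43, too wide to decide, and a change within cells stays open as well. In 1 of the 10 splits, the real one, was the camera p as small (1.86e-06, lowest other 0.000704), although the list also passed in 2 other splits (adjusted p = 0.0169 and 0.00921 by camera), and for the number of called lists 10 of 10 splits gave as many as the real 1, the highest other giving 5, with 10 splits too few for a share under 0.05.

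The arrays of a genotype are called technical replicates in the design text, yet Xist had a within-genotype SD of 2.26 on the log2 scale, rank 1 of all genes, with Eif2s3y at rank 2. Repeated arrays of 1 RNA per genotype would not give this spread, so the table argues against that reading. Separate RNA preparations from animals or pools of different sex are a candidate explanation, with both Xist and Y-linked transcripts present in 4 arrays. Xist at 7.56 or more together with Eif2s3y at 6.18 or more in these 4 arrays argues against 1 animal behind any of them. How many animals stand behind each array otherwise stays open.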
